A study of Mus musculus with 19 samples.

How the data were processed

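RNA from 19 mouse mammary tumours was measured on 2-colour oligonucleotide arrays, 1 array per tumour. Per the labels, the tumours were mammary adenocarcinomas of FVB mice carrying the simian virus 40 T antigen under the rat C3(1) promoter, a transgene that drives tumours of the mammary epithelium. Per the labels, 7 tumours were untreated and 12 came from mice given carboplatin and paclitaxel for 2 or 3 weeks, of which 3 were called responders and 9 non-responders. How response was judged, and when, is not given in the sources used here. Tumour RNA was labelled with Cy5 and a whole-mouse reference RNA with Cy3 on every array, per the labels, so no dye was swapped and a dye effect of a spot does not cancel within an array, although it does in a difference between tumours. RNA was extracted with a column kit, per the labels' protocols, which refer to methods articles for the other steps.

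The deposited values are log2 ratios, 1 per spot and array, as far as the values show; the log base, the direction of the ratio, any centring and the meaning of an exact 0 are not given in the sources used here. The scanner, background correction, within-array normalization and filters used by the authors are not given in the sources used here either. A log2 scale was inferred because the values reach further from 0 than log10 or natural-log ratios of a scanner would. The direction, tumour over reference, is likely rather than stated: genes of the liver were strongly negative, such as Fabp1 and Apoa1 with means of -6.85 and -4.64 in untreated tumours. The arrays correlated with each other at 0.568 to 0.847, a range that would be the same with the ratio turned. If the ratio ran the other way, the sign of each difference given here would turn. Values were not centred per gene. Array medians lay between -0.081 and 0.009. They were -0.031, -0.010, -0.053, -0.056, -0.015, -0.052 and -0.017 in untreated replicates 1 to 7, -0.023, 0.004 and -0.023 in responders 1 to 3, and -0.007, 0.009, -0.009, -0.038, -0.030, -0.065, -0.081, -0.002 and -0.002 in non-responders 1 to 9. The SD of the ratios over an array was 0.975 to 1.47. Replicates were numbered in accession order, which names a tumour and pairs nothing.

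Each array held 45220 spots, of which 738 to 4115 (1.63% to 9.10%) were listed at exactly 0, many times more than at the next most frequent value (58 to 310 spots). An exact 0 was therefore taken as a spot without a measurement. The platform annotation named 1 gene for 33653 spots, several for 56 and none for 11511. Only spots with 1 gene were used, giving 19087 genes, 8343 of them with over 1 spot. Of the annotation's gene identifiers, 99.6% matched the gene table of assembly GRCm38.p6, which changed 0 symbols and was used only for names and gene spans. Spots measured on at least 70% of the arrays in a fit were kept (32472 spots), and the spots of a gene were averaged, which left 18553 genes in fits of all arrays and 18624 in the fit of the treated arrays. Over the 223 genes with at least 8 spots, the median SD between spots of a gene within an array was 0.385, beside 0.502 between tumours of a group. Where the spots of a named gene went in opposite directions, the text says so. Signal over background is not analysed here, so precision rests on the number of arrays and the spread between tumours.

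Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. Treated tumours were compared with untreated ones in a fit of 2 groups. Responders were compared with non-responders, and each of these with untreated tumours, in a fit of 3 groups over all 19 arrays. Tumours after 3 weeks were compared with those after 2 weeks among the 12 treated tumours, with response as a covariate. In all, 27 gene lists for the tissue, the drugs and other cell types of a tumour piece were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. They covered mitosis, DNA replication, DNA repair, p53 targets, apoptosis regulators, drug handling, tubulin and microtubule regulators, interferon-stimulated genes, antigen presentation, T and NK cells, B and plasma cells, macrophages, neutrophils, mast cells, endothelium, fibroblasts and collagen matrix, adipocytes, skeletal muscle, erythroid cells, squamous epithelium, basal and myoepithelial cells, luminal epithelium, milk proteins, epithelial-mesenchymal transition (EMT), hypoxia and glycolysis, protein folding and stress, and immediate-early response. They held 633 genes, of which 590 were measured. The p of camera takes genes as nearly independent, so it was also computed with a correlation estimated for each list.

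The design, tests, lists, most alternatives and the rule for naming genes were chosen before the data were examined. The rule took the 10 genes with the largest positive and the 10 with the largest negative log2 difference among those that passed, or, with fewer than 5 passing, the 5 higher and 5 lower with the smallest p, leaving out uncharacterised symbols. It added the 4 members with the smallest p of each list that passed, 2 of each other list discussed by gene, and Cdkn1a, Abcb1a, Abcb1b, Tubb3, Ercc1 and Mki67 in treated against untreated tumours. Which of the lists that did not pass are discussed by gene was chosen after values, and the single far-off values among them, had been seen. Added after seeing the data were exact two-sided permutation tests of a list's score (the mean over its members of each tumour's log2 ratio, relative to the mean of all 19), a principal component analysis, and settings with zeros kept as values, with the style of the sample titles as a block or within each style, and without untreated replicates 2 and 4. Titles name the mouse after a hyphen on 7 arrays (2 untreated, 2 non-responders, 3 responders) and after another sign on 12 (5 untreated, 7 non-responders). What the style marks is not given in the sources used here; scan dates and slides were not used here.

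According to the labels the tumours came from 18 mice: 1 mouse gave non-responder 1 and responder 3. The deviations of these 2 tumours from their group means correlated at 0.163, a value reached by 7 of 171 pairs of tumours. Taking out group means pushes pairs within a group towards negative values, and this pair lies across groups. Its rank among all pairs may therefore overstate how alike the 2 tumours were. They were treated as separate samples, with alternatives that left both out or averaged them. Other alternatives changed the filter, the rule for several spots, the scaling between arrays, the variance model and the array weights, and left out each array in turn. The fits were tested on simulated data made from the real genes, with 100 genes shifted by 1 and 100 by 2 on the log2 scale. Noise was drawn independently for each gene and array, so correlation between genes and differences between sets of arrays were left out. The share recovered was 42% and 77% for treated against untreated tumours, 24% and 68% for responders against non-responders, 26% and 77% for 3 against 2 weeks, 45% and 74% for non-responders against untreated tumours, and 18% and 65% for responders against untreated tumours, with 5 to 7 unshifted genes called and 0 shifted genes called with the wrong sign. Counts of genes were compared with 100 splits of the same tumours, the real split included, and permutation tests over genes used 100000 resamples.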

Results

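The series set chemotherapy-treated mammary tumours of a genetically engineered mouse against untreated ones, under a title about predicting drug response in human cancers from such mice. The C3(1)-Tag mouse expresses a viral oncoprotein that binds p53 and the retinoblastoma protein in mammary epithelium. Carboplatin is a platinum drug that crosslinks DNA, and paclitaxel is a taxane that stabilises microtubules. Each of 19 tumours was measured once against a common reference RNA: 7 untreated, 9 treated non-responders (4 after 2 weeks and 5 after 3) and 3 treated responders (1 after 2 weeks and 2 after 3). All values are differences of log2 ratios between groups, given with the standard error, and the number of arrays limits their precision. The first principal component of 14984 genes measured on all arrays carried 16.6% of the variance and ran from -7.68 to 40.5 in treated and from -69.4 to 3.13 in untreated tumours (exact permutation p = 9.923e-05). The third component (9.57%) parted the 7 arrays with a hyphen in the title (12.4 to 49.9) from the other 12 (-48.5 to 3.10), with an exact permutation p of 0.00132 within groups. All 3 responders were among these 7 arrays. For components 1, 2, 4 and 5 the exact permutation p of the title style within groups was 0.979, 0.857, 0.0331 and 0.319, not adjusted for the number of components. With the group in the limma model, 18 of 18553 genes passed between the title styles, with 2005 at an unadjusted p under 0.05 beside 928 given by chance.

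The first comparison asked how tumours after 2 to 3 weeks of carboplatin and paclitaxel differed from untreated ones, whatever the response. Most treated tumours came from mice with higher numbers in the titles than any untreated mouse. What these numbers follow is not given in the sources used here. Cohort, age and time of harvest were not taken into account, so the treatment cannot be told apart from a difference in these. As lists, genes of macrophages, interferon response and antigen presentation were higher in treated tumours, together with p53 target, fibroblast matrix and basal genes, while genes of DNA replication were lower. None of these lists passed with an estimated correlation (adjusted p between 0.275 and 0.557 with an estimated correlation). Among the genes that rose most were Arg1, the arginase of alternatively activated macrophages (1.97 ± 0.44, 3.91-fold, adjusted p = 0.0207), and Ly6c2, a surface antigen of inflammatory monocytes (1.76 ± 0.32, adjusted p = 0.00998). The lysozyme Lyz1 rose likewise (1.73 ± 0.33, adjusted p = 0.0114). Each of these 3 lay above the untreated mean in 12 of 12 treated tumours. Among those that fell most were Chil3, a chitinase-like protein secreted by activated macrophages (-2.41 ± 0.47, 5.31-fold lower, adjusted p = 0.0119), and Egr2, a zinc finger transcription factor (-2.09 ± 0.41, adjusted p = 0.0126). Another was Vldlr, a lipoprotein receptor (-1.71 ± 0.27, adjusted p = 0.00386). All 12 treated tumours lay below the untreated mean for each of them.

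In total, 678 of 18553 genes passed, 410 higher and 268 lower in the 12 treated than in the 7 untreated tumours. Of these, 115 rose and 44 fell by over 2-fold. The other genes with the largest rises were Phf8-ps, a pseudogene (2.59 ± 0.52, measured in 10 treated and 4 untreated tumours), the plasminogen activator inhibitor Serpinb2 (1.83 ± 0.46), the mesenchymal homeobox gene Prrx2 (1.76 ± 0.36) and the extracellular matrix glycoprotein Efemp1 (1.75 ± 0.40). They also included the glucuronosyltransferase Ugt1a6b (1.69 ± 0.26, with 2 spots at 0.67 and 1.79), the gelatinase Mmp2 (1.65 ± 0.44) and the matrix protein Tgfbi (1.62 ± 0.40). Their adjusted p lay between 0.00386 and 0.0418. With only spots measured on every array or with the most variable spot, Ugt1a6b stood at 0.67 and did not pass. The other genes with the largest falls were the iron-binding melanotransferrin Meltf (-2.65 ± 0.56), Tpra1 (-2.24 ± 0.60), Igfl3 (-2.23 ± 0.48) and Shisa2 (-1.49 ± 0.29). The olfactory receptor genes Olfr1295 (-2.44 ± 0.57), Olfr971 (-1.60 ± 0.24) and Olfr1221 (-1.55 ± 0.31) fell as well, and adjusted p of the falls lay between 0.00386 and 0.0411. Ly6c2, Lyz1, Ugt1a6b and the olfactory receptor genes belong to families of similar sequence, and whether their probes tell the members apart was not tested.

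**Figure D1:**
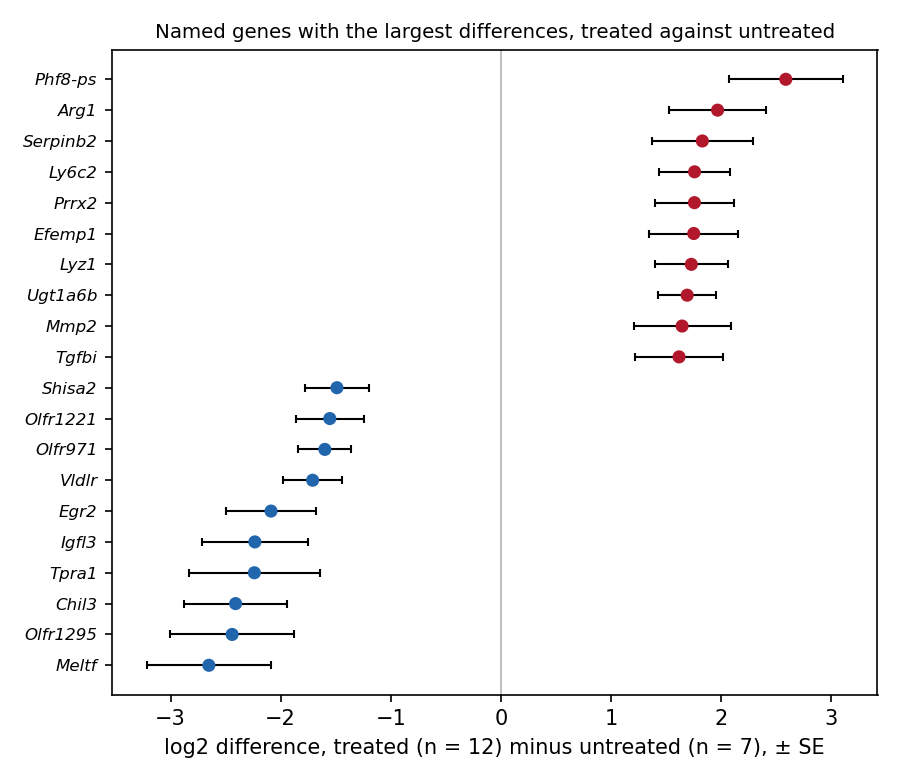
The 10 genes that rose most and the 10 that fell most among those that passed, as the log2 difference between 12 treated and 7 untreated tumours with its standard error (bars). Rises ran from 1.62 (Tgfbi) to 2.59 (Phf8-ps) and falls from -1.49 (Shisa2) to -2.65 (Meltf).

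Macrophage and monocyte markers rose as a list (median 0.66, adjusted p = 3.9e-09, and adjusted p = 0.275 with an estimated correlation). Of 24 measured members, 8 rose over all genes and 15 adjusted over the list alone. Besides Arg1 and Lyz1, the IgG receptor Fcgr3 (1.13 ± 0.20, adjusted p = 0.00764) and the Fc receptor gamma chain Fcer1g (1.03 ± 0.22, adjusted p = 0.0155) rose. Interferon-stimulated genes rose too (median 0.70, adjusted p = 4.23e-09, and adjusted p = 0.275 with an estimated correlation). All 28 measured members were positive, of which 5 passed over all genes and 15 adjusted over the list alone. Among them were the antiviral genes Ifit3 (0.81 ± 0.18), Bst2 (1.45 ± 0.33), Oas1a (0.67 ± 0.17) and the ubiquitin-like modifier Isg15 (0.81 ± 0.21). Antigen presentation genes rose by a median of 0.54 (adjusted p = 6.93e-06, and adjusted p = 0.275 with an estimated correlation), with 3 of 20 passing and 6 adjusted over the list alone. The immunoproteasome subunits Psmb10 (0.81 ± 0.19) and Psmb8 (0.64 ± 0.18) and the class II gene H2-Oa (0.97 ± 0.26) rose, and the nonclassical class I gene H2-T23 stood at 0.94 ± 0.27 without passing (adjusted p = 0.0532). For all 3 lists the mean score lay above the untreated mean in 12 of 12 treated tumours, with exact permutation p of 0.000834, 0.000814 and 0.00101. Within the 7 hyphen-titled arrays the medians were 0.42, 0.47 and 0.20, and within the other 12 they were 0.79, 0.79 and 0.64. Antigen presentation did not pass within the hyphen-titled arrays (adjusted p = 0.458).

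Markers of other immune and vascular cells did not pass as lists in camera. The T and NK cell list had a median of 0.40 (adjusted p = 0.0786) and passed in camera on ranks (adjusted p = 0.0339). Its leading members were the granule protease Gzmb at 1.16 ± 0.40 and the transcription factor Eomes at -0.91 ± 0.37, neither of which passed. Its score was higher by 0.33 in treated tumours (exact permutation p = 0.0765). The neutrophil list had a median of 0.23 (adjusted p = 0.169) and a score difference of 0.44 (exact permutation p = 0.0689), with the collagenase Mmp8 at 1.73 ± 0.58 and Stfa3 at 1.42 ± 0.61, neither of which passed. Medians were 0.22 for B and plasma cells (adjusted p = 0.651), -0.08 for mast cells (adjusted p = 0.779) and -0.10 for the 6 measured of 12 erythroid genes (adjusted p = 0.74). Endothelial markers had a median of 0.17 (adjusted p = 0.074), and 3 of 22 members rose (4 adjusted over the list alone), including the TGF-beta co-receptor Eng (0.81 ± 0.19) and the clotting factor carrier Vwf (0.90 ± 0.24).

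Fibroblast and collagen matrix genes rose by a median of 0.76 (adjusted p = 3.89e-05, and adjusted p = 0.557 with an estimated correlation). Of 26 measured members, 23 were positive, Mmp2 passed over all genes and 3 passed adjusted over the list alone. The next members were Fbln1 at 1.53 ± 0.46, the crosslinking enzyme Loxl1 at 1.14 ± 0.35 and Col5a1 at 1.07 ± 0.40. The score was higher than the untreated mean in 9 of 12 treated tumours (exact permutation p = 0.0383, and 0.104 adjusted over the lists), with medians of 0.47 and 0.86 within the title styles. The list did not pass in the fry test (adjusted p = 0.124). EMT genes rose by a median of 0.54 (adjusted p = 0.000106, and adjusted p = 0.337 with an estimated correlation), with 2 of 22 passing and 7 higher and 1 lower adjusted over the list alone. The growth factor Tgfb3 (0.76 ± 0.18) and Tgfbi passed, and the proteases Mmp13 (2.06 ± 0.62) and Mmp3 (1.68 ± 0.53) did not. The EMT median was 0.32 in the hyphen-titled arrays, where the list did not pass (adjusted p = 0.241), and 0.56 in the others.

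Basal and myoepithelial genes rose by a median of 0.32 (adjusted p = 0.00805, and adjusted p = 0.36 with an estimated correlation), and luminal genes did not pass (median -0.21, adjusted p = 0.361). Of 21 basal genes, 3 rose over all genes, and 5 rose and 1 fell adjusted over the list alone. The basal keratins Krt14 (1.03 ± 0.27) and Krt17 (0.93 ± 0.24) and the smooth-muscle calponin Cnn1 (1.59 ± 0.43) passed, while the basal transcription factor Trp63 (0.91 ± 0.27) did not and its spots went in opposite directions. Among luminal genes, the receptor Kit (-0.95 ± 0.27) and the transcription factor Elf5 (-1.30 ± 0.45) had the smallest p. Neither passed over all genes, and Kit fell adjusted over the list alone (adjusted p = 0.0491), 1 of 22 members. Genes of cornified squamous epithelium rose as a list (median 0.57, adjusted p = 0.00365, and adjusted p = 0.557 with an estimated correlation), with 1 of 19 passing and 2 adjusted over the list alone. The transglutaminase Tgm1 passed (1.24 ± 0.23), and Krt6a (1.29 ± 0.38), Tgm3 (0.95 ± 0.34) and Krtdap (0.86 ± 0.35) did not. Skeletal muscle genes had a median of 0.53 (adjusted p = 0.00269, and adjusted p = 0.641 with an estimated correlation). In limma 0 of 20 members passed over all genes or adjusted over the list alone, with Mybpc2, Eno3, Mb and Actn3 between 0.84 and 1.12. Medians within the hyphen-titled arrays and within the others were 0.62 and 0.37 for basal genes. They were 1.20 and -0.01 for squamous genes (adjusted p = 0.954 in the others) and 1.62 and -0.16 for muscle genes (adjusted p = 0.552 in the others). Without untreated replicate 1 the squamous median was 0.40 (adjusted p = 0.1) and the muscle median 0.36 (adjusted p = 0.0941), so neither list passed. The muscle median was 0.87 without untreated replicate 5 and 0.32 with quantile normalization.

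**Figure D2:**
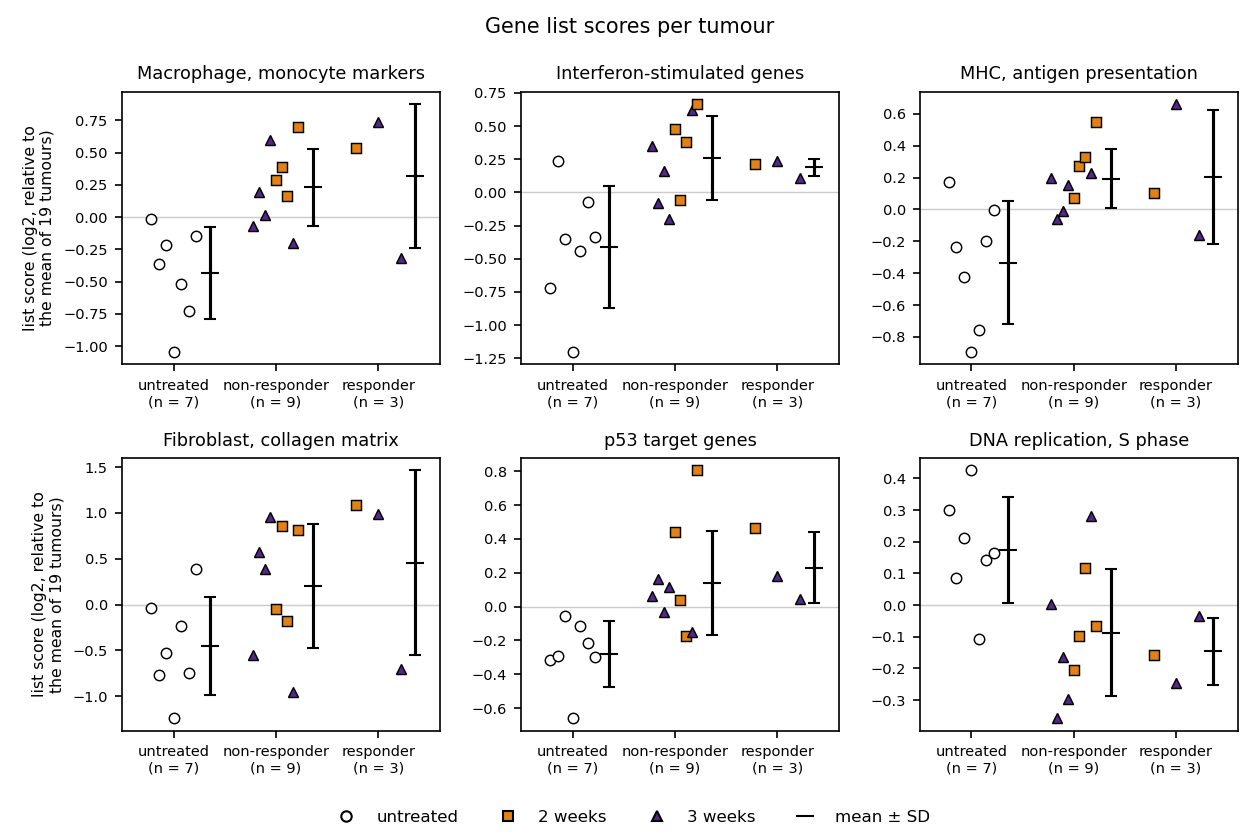
Score of 6 gene lists in each of 19 tumours, as the mean log2 ratio of the members relative to the mean of all tumours, with squares for 2 weeks and triangles for 3 weeks and with the mean and SD of untreated tumours, non-responders and responders. Treated tumours lay above the untreated mean in 12 of 12 cases for macrophage, interferon, antigen presentation and p53 target genes and in 9 of 12 for fibroblast matrix genes, and in 1 of 12 for DNA replication genes.

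DNA replication genes fell (median -0.29, adjusted p = 0.000106, and adjusted p = 0.275 with an estimated correlation). Of 29 measured members, 3 fell over all genes, and 9 fell and 2 rose adjusted over the list alone. The replicative helicase subunits Mcm6 (-0.90 ± 0.17) and Mcm4 (-0.92 ± 0.18) and the clamp loader subunit Rfc4 (-0.81 ± 0.22) passed. Mcm4 did not pass with zeros kept as values (-0.42, adjusted p = 0.325), with the open filter (-0.72, adjusted p = 0.325), or within the hyphen-titled arrays (-0.00375, adjusted p = 0.997). The licensing factor Cdt1 stood at -0.60 ± 0.17 (adjusted p = 0.0501). Their score lay below the untreated mean in 11 of 12 treated tumours (exact permutation p = 0.00496), with medians of -0.31 and -0.24 within the title styles. Mitosis genes fell as a list too (median -0.12, adjusted p = 0.0122, and adjusted p = 0.641 with an estimated correlation), with 1 of 29 passing and 2 adjusted over the list alone. The kinetochore motor Cenpe fell (-0.70 ± 0.18, with spots that went in opposite directions), and Nusap1 (-0.76 ± 0.28), Cenpf (-0.57 ± 0.23) and the proliferation marker Mki67 (-0.50 ± 0.14, adjusted p = 0.0552) did not pass. The mitosis list did not pass without untreated replicate 1 (adjusted p = 0.0754) or untreated replicate 4 (adjusted p = 0.0715), and its median was -0.19 without untreated replicate 6. It did not pass with quantile normalization (adjusted p = 0.103), nor within the 12 arrays without the hyphen, where its median was 0.08 (adjusted p = 0.841) beside -0.45 in the hyphen-titled arrays. DNA repair genes did not pass as a list (median -0.07, adjusted p = 0.406), but the mismatch repair gene Msh6 (-0.80 ± 0.14, adjusted p = 0.00725) and the helicase Blm (-0.55 ± 0.12, adjusted p = 0.0182) fell. Adjusted over the list alone 2 of 26 rose and 3 fell.

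Genes that p53 is known to activate rose (median 0.41, adjusted p = 3.89e-05, and adjusted p = 0.275 with an estimated correlation), with 4 of 26 passing over all genes and 9 adjusted over the list alone. They were Ei24 (0.76 ± 0.17), the cyclin Ccng1 (1.04 ± 0.26), Phlda3 (0.89 ± 0.23) and Trp53inp1 (1.08 ± 0.27), each above the untreated mean in 12 of 12 treated tumours. The cell cycle inhibitor Cdkn1a stood at 0.98 ± 0.29 and did not pass (adjusted p = 0.06). The list's medians within the title styles were 0.40 and 0.33. Drug and platinum handling genes rose by a median of 0.28 (adjusted p = 0.00805, and adjusted p = 0.275 with an estimated correlation), with 1 of 26 passing and 2 adjusted over the list alone. The glutathione transferase Gsta4 rose (1.23 ± 0.29), and Gstm2 (1.41 ± 0.42), Abcc5 (0.73 ± 0.24) and Abcg2 (0.55 ± 0.21) did not pass. Within the hyphen-titled arrays the list's median was 0.23 and it did not pass (adjusted p = 0.102), beside 0.38 in the others. Neither gene of the multidrug transporter P-glycoprotein passed, with Abcb1a at 0.89 ± 0.58 (adjusted p = 0.417) and Abcb1b at 0.56 ± 0.26 (adjusted p = 0.232, spots in opposite directions). The excision repair gene Ercc1 (0.45 ± 0.15, adjusted p = 0.0995) and the neuronal tubulin Tubb3 (0.20 ± 0.20, adjusted p = 0.627) did not pass either.

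The remaining lists did not pass between treated and untreated tumours. Apoptosis regulators had a median of -0.02 (adjusted p = 0.361), although the caspase gene Casp2 (-0.78 ± 0.19, adjusted p = 0.0284) and the death ligand Tnfsf10 (-1.33 ± 0.33, adjusted p = 0.0329) fell, 2 of 22 members also adjusted over the list alone. Tubulin and microtubule genes had a median of 0.18 (adjusted p = 0.361), with 0 of 24 passing in limma and Tuba4a (0.46 ± 0.17) and Tubg1 (0.42 ± 0.16) as the members with the smallest p. Protein folding genes had a median of 0.13 (adjusted p = 0.486), with the disulfide isomerase Pdia4 higher (0.93 ± 0.21, adjusted p = 0.0231), Dnajb9 at -0.66 ± 0.19 (adjusted p = 0.0558), and 3 higher and 3 lower of 23 adjusted over the list alone. Medians were 0.38 for adipocyte markers (adjusted p = 0.281) and -0.03 for hypoxia genes (adjusted p = 0.651). For milk protein genes the median was 0.09 and the mean 0.02 while the test ran the other way (adjusted p = 0.74), and for immediate-early genes the median was 0.03 while the mean was -0.04 and the test negative (adjusted p = 0.86), with Egr2 as the member that fell over all genes, and 2 lower and 1 higher adjusted over the list alone.

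By limma, 3714 genes had an unadjusted p under 0.05, beside 928 given by chance, and 12 of 27 lists passed, 10 higher and 2 lower. None of the 12 passed with an estimated correlation, 8 passed in limma's self-contained fry test, and exact permutation of the scores gave 8 lists with an adjusted p under 0.05 (smallest 0.00737). The mitosis, fibroblast matrix, muscle and squamous lists failed both. The count of genes rested on few arrays: it was 1183 without untreated replicate 1, 212 without untreated 4, 222 without untreated 6, 346 without untreated 2 and 382 without untreated 5. It was 395 without non-responder 4, 405 without non-responder 9, 408 without responder 1, 412 without non-responder 5 and 446 without responder 2. Of the 50 named genes that passed, 20 passed whichever single array was left out, and all 50 kept their sign in each setting tried. In the smaller sets of arrays most of the 50 calls were lost. All 50 were lost with 3-week treated tumours alone and within the hyphen-titled arrays, and all but Serpinb2 with 2-week treated tumours alone. These 20 were Ly6c2, Prrx2, Lyz1, Ugt1a6b, Meltf, Chil3, Igfl3, Egr2, Vldlr, Olfr971, Olfr1221, Shisa2, Mcm6, Mcm4, Msh6, Blm, Ifit3, Fcgr3, Fcer1g and Tgm1. All 20 were thus lost in each of these smaller sets. Besides, Mcm4 was lost in the other settings named above for it. Ugt1a6b was lost in those named above for it (adjusted p = 0.169 and 0.234) and with zeros kept as values (0.74, adjusted p = 0.0844). Of the 50, 27 were lost without untreated 6, 25 without untreated 4, 17 each without untreated 2 and untreated 5, 16 each without responder 1 and non-responder 9, 14 each without non-responders 4 and 5, 13 without responder 2, and 9 or fewer without each other array. Within the 7 hyphen-titled arrays 2 genes passed, within the other 12 arrays 262 passed (158 of them among the 678), and with the title style as a block 793 passed. Without untreated 2 and 4 together 42 passed (40 of them among the 678), and with only spots measured on every array 1313 passed. Set against untreated tumours, the 2-week tumours alone gave 3 genes and the 3-week tumours alone gave 0, with 2906 at an unadjusted p under 0.05. The 3 were Nme4 (1.65), Serpinb2 (2.85) and the myosin gene Myo1f (1.23), and the 2 of the hyphen-titled arrays were Tmem45a2 (3.17) and E130114P18Rik (5.64), all given after their values were seen.

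Set against untreated tumours separately, both response groups held genes that passed in limma. In the 9 non-responders 283 genes passed, 163 higher and 120 lower, with 3218 at an unadjusted p under 0.05. In the 3 responders 14 passed, 6 higher and 8 lower, with 2995 at an unadjusted p under 0.05. The 14 included the macrophage-secreted Chil3 (-3.88), the lysosomal protease Ctsd (1.62) and the transcriptional regulator Trim33 (-1.49), singled out after their values were seen because they were the 3 that passed without any one of 8 arrays named below. Without the mouse that gave 2 tumours Chil3 did not pass, and with the title style as a block Ctsd and Trim33 did not. The 2 counts do not show that the groups differ, since they come from different numbers of tumours against the same 7 controls; the direct test is given next. The count for non-responders was 607 without untreated 1, 33 without untreated 4, 34 without untreated 6, 62 without non-responder 4, 79 without non-responder 5, and 82 without untreated 5. It was 103 without untreated 2, 110 without non-responder 9, 119 without non-responder 6, 120 without non-responder 3, 146 without non-responder 7, 168 without responder 3 and 173 without responder 1. The count for responders was 396 without untreated 1, 140 without untreated 7, 8 without non-responder 8, 7 without non-responder 1 or responder 3, 5 without non-responder 6, and 3 without any one of untreated 2, 3, 4 or 6 or non-responders 3, 5, 7 or 9. With only spots measured on every array the counts were 694 and 366, with estimated array weights 607 and 538, and without the mouse that gave 2 tumours 167 and 5 (Ankrd23, Ctsd, Fam184a, Mybpc2 and Trim33). The count for responders was also 25 with the most variable spot of each gene, 47 with a trend and a robust variance, 39 with zeros kept as values and 1 (Chil3) with the title style as a block. Within the hyphen-titled arrays both counts were 0, with 1325 and 1707 genes at an unadjusted p under 0.05.

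The second comparison asked how responders differed from non-responders, the contrast closest to the drug response in the series title. Genes of skeletal muscle and cornified squamous epithelium were higher as lists in the 3 responders than in the 9 non-responders, as were genes of protein folding, and genes of mitosis were lower. None of the 4 lists passed with an estimated correlation (adjusted p between 0.16 and 0.74), in the fry test or by adjusted exact permutation (smallest 0.245), and no single gene passed. The largest difference among the genes with the smallest p was that of Myh4, the fast myosin heavy chain of skeletal muscle, at 4.29 ± 1.07 (adjusted p = 0.528), with a mean of 0.73 ± 2.34 (SD, n = 3) in responders and -3.56 ± 1.74 (SD, n = 9) in non-responders. The other higher genes were Paqr3 (1.38 ± 0.26), Iffo2 (1.71 ± 0.38), Olfr1168 (1.69 ± 0.36) and the chemokine Ccl21c (2.10 ± 0.49). The lower ones were Eml2, a microtubule-associated protein (-1.62 ± 0.28, adjusted p = 0.316), and Gucy1b1, a subunit of the nitric oxide receptor (-1.23 ± 0.25). They also included Tdo2, which degrades tryptophan (-2.24 ± 0.47), Cuzd1 (-1.78 ± 0.38) and the clotting factor F12 (-2.61 ± 0.60). None of these passed.

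All 20 skeletal muscle genes were positive in responders (median 1.06, adjusted p = 3.25e-13, and adjusted p = 0.422 with an estimated correlation). Of them 0 passed over all genes in limma and 8 adjusted over the list alone, with the calcium buffer Pvalb at 2.75 ± 0.81, the enolase Eno3 at 1.68 ± 0.52 and the myosin-binding protein Mybpc2 at 1.32 ± 0.38 beside Myh4. The muscle median was 0.56 without responder 2. The muscle score was 1.42, 1.79 and 0.07 in responders 1 to 3 (1.09 ± 0.90, SD) and -0.06 ± 0.47 in 9 non-responders, of which non-responder 2 stood at 1.02 (exact permutation p = 0.00909, 0.245 adjusted over the 27 lists). Squamous genes were higher by a median of 0.62 (adjusted p = 4.2e-06, and adjusted p = 0.444 with an estimated correlation), with 17 of 19 positive and 2 passing adjusted over the list alone. Krt10, a keratin of cornifying cells, stood at 1.80 ± 0.48, the cornified envelope protein Lor at 2.03 ± 0.59, Lce1a1 at 0.94 ± 0.37 and the desmoglein Dsg1a at 1.57 ± 0.61. Protein folding genes were higher by a median of 0.34 (adjusted p = 1.15e-05, and adjusted p = 0.16 with an estimated correlation), with 19 of 23 positive and 1 passing adjusted over the list alone. Herpud1, which takes part in degrading misfolded proteins, stood at 0.75 ± 0.21, the chaperone Calr at 0.62 ± 0.23, Sdf2l1 at 0.87 ± 0.34 and Chac1 at 0.69 ± 0.31. Mitosis genes were lower by a median of -0.33 (adjusted p = 0.000139, and adjusted p = 0.74 with an estimated correlation), with 26 of 29 negative and 0 passing in limma over all genes or adjusted over the list alone. The kinesin Kif20a (-0.64 ± 0.24), the cyclin Ccna2 (-0.57 ± 0.27) and the kinase Cdk1 (-0.65 ± 0.31) were negative and Ndc80 positive (0.62 ± 0.28, spots in opposite directions). Exact permutation p of the squamous, folding and mitosis scores were 0.0227, 0.0273 and 0.109, and none passed after adjustment.

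**Figure D3:**
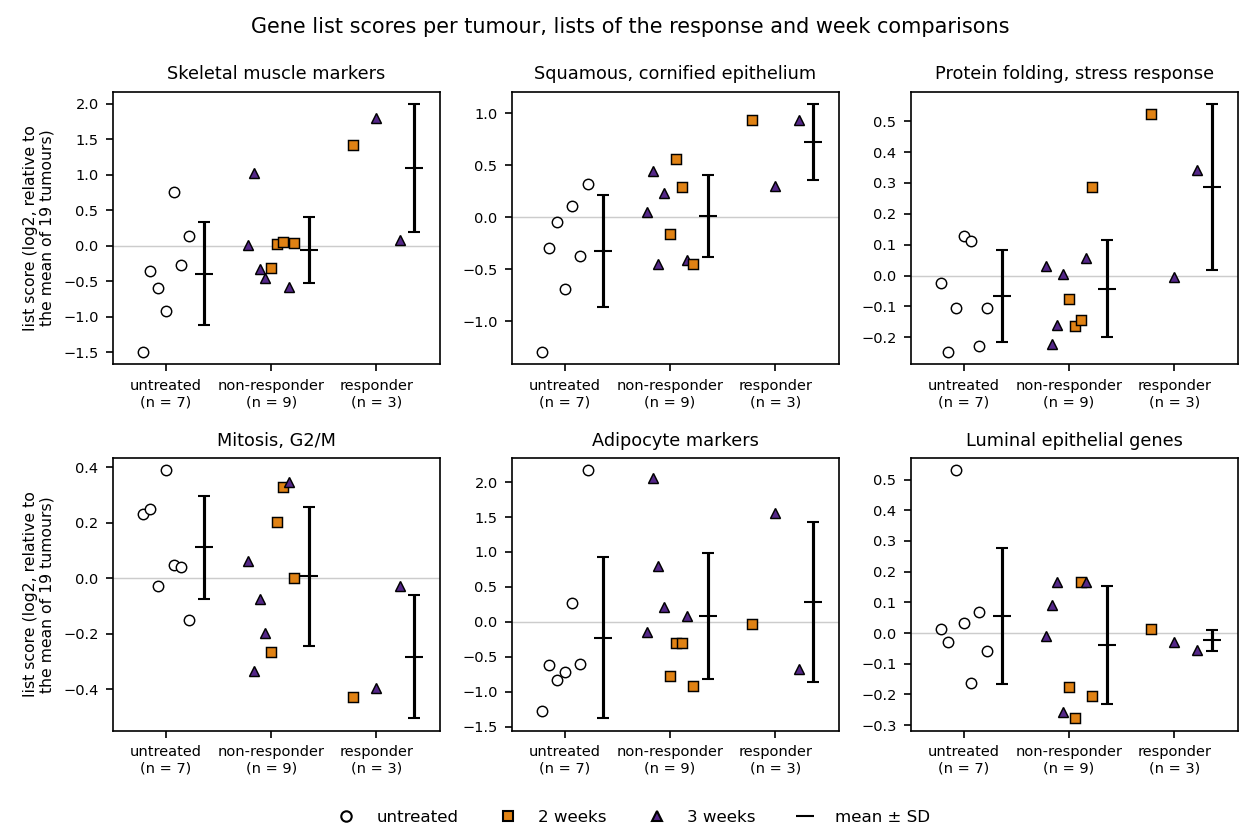
Score of 6 gene lists in each of 19 tumours, as the mean log2 ratio of the members relative to the mean of all tumours, with squares for 2 weeks and triangles for 3 weeks and with the mean and SD of untreated tumours, non-responders and responders. The 3 responders lay above the mean of the 9 non-responders for skeletal muscle, squamous and protein folding genes and below it for mitosis genes, and the muscle score had a mean of 1.09 in responders.

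The other 23 lists did not pass between responders and non-responders. Those closest to the drugs had medians of 0.03 for p53 targets (adjusted p = 0.478; Ei24 0.48 ± 0.22, Phlda3 0.60 ± 0.30) and -0.01 for DNA repair (adjusted p = 0.825; Fanca 0.61 ± 0.26, Ddb2 -0.50 ± 0.22). They were 0.11 for drug handling (adjusted p = 0.611; Gstp1 0.44 ± 0.24, Nqo1 0.45 ± 0.25) and -0.12 for tubulin and microtubule genes (adjusted p = 0.513; Tubb2a -0.54 ± 0.25, Mapre3 0.69 ± 0.34). Medians were -0.02 for DNA replication, 0.15 for macrophages, -0.07 for interferon-stimulated genes and 0.27 for fibroblast matrix, with adjusted p of 0.825, 0.478, 0.621 and 0.188. In limma 0 of 18553 genes passed, with 1174 at an unadjusted p under 0.05 beside 928 given by chance and a smallest adjusted p of 0.316. The count was 12 without responder 1, 7 without responder 2 and 1 without responder 3, and 4 lists became 9 without responder 3. The 1 gene was Fam184a (-2.64), given like the other single genes here after its value was seen. Within the hyphen-titled arrays, which hold all 3 responders and 2 non-responders, the medians were 0.46 for muscle, 0.29 for squamous, 0.36 for folding and -0.14 for mitosis genes. Of these, the mitosis list did not pass (adjusted p = 0.211) and 8 lists passed in all. Over all arrays none of the 4 lists passed in the fry test. With both tumours of the mouse that gave 2 left out, 8 lists and 1 gene (Fam184a, -2.76) passed, and with 3-week tumours alone 1 gene passed (Krt88, -2.68).

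The third comparison set tumours after 3 weeks of treatment against those after 2 weeks, with response taken into account. Adipocyte genes were higher after 3 weeks, and p53 target, macrophage, fibroblast matrix and basal genes were lower as lists. None of the 5 lists passed with an estimated correlation (adjusted p = 0.872 for each), in the fry test or by adjusted exact permutation (smallest 0.665), and no single gene passed. All 18 adipocyte genes were positive (median 0.84, adjusted p = 3.17e-11, and adjusted p = 0.872 with an estimated correlation). The lipid droplet proteins Plin4 (2.39 ± 0.78) and Cidec (2.21 ± 0.87), the adipokine Adipoq (1.58 ± 0.63) and the fatty acid synthesis enzyme Acaca (0.59 ± 0.22, spots in opposite directions) led the list. Its score lay above the 2-week mean in 6 of 7 tumours (exact permutation p = 0.0492, 0.665 adjusted over the lists). This permutation did not take response into account. The score was highest in non-responder 2 (2.06) and responder 2 (1.55), and lay between -0.67 and 0.80 in the other 3-week tumours. Untreated replicate 7 stood at 2.17, above each treated tumour. Which cells the difference came from was not tested.

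The 4 lower lists each had an adjusted p of 0.00965, and an adjusted p of 0.872 with an estimated correlation. Fibroblast matrix genes had a median of -0.50, with 23 of 26 negative, Lox at -1.35 ± 0.57, the fibronectin Fn1 at -0.50 ± 0.25, Col6a1 at -0.66 ± 0.35 and Col12a1 at 1.41 ± 0.67. For p53 targets the median was -0.27, with 20 of 26 negative: Eda2r at -0.86 ± 0.28, Ccng1 at -0.75 ± 0.28, Zmat3 at -0.89 ± 0.34 and Dcxr at -0.62 ± 0.24. Basal genes had a median of -0.27, with 18 of 21 negative: the growth factor Nrg1 at -0.67 ± 0.21, the laminin Lama3 at -0.49 ± 0.23, the Notch ligand Jag2 at -0.51 ± 0.28 and the kinase Mylk at -0.41 ± 0.26. Macrophage markers had a median of -0.21, with 20 of 24 negative: the receptor Adgre1 at -0.70 ± 0.21, Clec7a at -1.04 ± 0.37, Lyz1 at -0.73 ± 0.35 and Fcgr1 at -0.42 ± 0.20. Interferon-stimulated genes did not pass (median -0.09, adjusted p = 0.316), with Irf9 at -0.74 ± 0.22 (spots in opposite directions) and Irf7 at -0.92 ± 0.39. DNA replication genes did not pass either (median -0.06 and mean -0.03, with a test of positive sign and an adjusted p of 0.885), with Chaf1b at 0.49 ± 0.22 and Ccne2 at -0.51 ± 0.30. In none of the 5 lists did a member pass over all genes or adjusted over the list alone, or the list pass in the fry test.

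The genes with the smallest p in this comparison were Rag2 (0.73 ± 0.14), Gucy2e (1.83 ± 0.35), Pnma2 (1.08 ± 0.25), Lyrm7 (0.90 ± 0.21) and Rsl24d1 (0.63 ± 0.15) on the higher side. On the lower side they were the lysophosphatidic acid receptor Lpar3 (-1.62 ± 0.32), Stk31 (-1.49 ± 0.27), the G protein regulator Rgs20 (-1.39 ± 0.29), Ear6 (-1.54 ± 0.33) and Fxyd6 (-0.76 ± 0.17). None passed: limma called 0 of 18624 genes, with 830 at an unadjusted p under 0.05 beside 931 given by chance and a smallest adjusted p of 0.940. The adipocyte list passed whichever array was left out, and its median was 1.35 without the mouse that gave 2 tumours. The count of 5 lists was 1 without responder 1, 2 without non-responder 9, 3 without non-responder 1 or responder 3, and 8 without non-responder 7. It was also 8 with the title style as a block and 1 without the mouse that gave 2 tumours, where the matrix median was -0.21 and the macrophage median -0.14. With quantile normalization the p53 and macrophage lists did not pass (adjusted p = 0.0558 and 0.0648). The p53 list did not pass without responder 1 (adjusted p = 0.105), non-responder 5 (0.17) or non-responder 9 (0.598). The macrophage list did not pass without responder 1 (0.102), responder 3 (0.132), non-responder 8 (0.0824) or non-responder 9 (0.319). The matrix list did not pass without responder 1 (0.319), responder 3 (0.132), non-responder 1 (0.0569), non-responder 8 (0.195) or non-responder 9 (0.274). The basal list was lost without responder 1 (0.105), non-responder 1 (0.0569), non-responder 8 (0.0824) or non-responder 9 (0.193). Within the 7 treated tumours titled without the hyphen the medians were 0.68 for adipocyte, -0.26 for p53, -0.22 for macrophage, -0.33 for matrix and -0.18 for basal genes, and the last 3 lists did not pass (adjusted p = 0.141, 0.484 and 0.371).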

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

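The tests of explanations in this part were all chosen after the results were seen, and the comparison with other splits of the samples was chosen before. In groups of 4 to 10 tumours, a sample is given here when its gap to the nearest other tumour, divided by the range of the group, exceeded Dixon's 95% critical value. Chance gives about 1 in 20 such groups. Of 346 groups of values tested (146 named genes and 27 list scores), 28 had such a sample, or 8.09%. Part of the named genes had been chosen after their values were seen; with members of every list that did not pass named by the same rule, 49 of 494 groups had one (9.92%, 220 genes). Untreated replicate 4 was that sample in 6 groups, untreated 7 in 5, non-responder 2 in 4 and non-responder 4 in 3.

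Genes of macrophages, interferon response, antigen presentation and collagen matrix were higher in treated tumours as lists, none of which passed with an estimated correlation (adjusted p = 0.275 for 3 of them and 0.557 for matrix). The scores of all 10 lists of other cell types changed unequally (exact permutation p = 0.0120). They differed by 0.69 for macrophages, 0.72 for matrix, 0.62 for muscle, 0.44 for neutrophils and 0.36 for adipocytes. Differences were 0.33 for T and NK cells, 0.21 for endothelium, 0.03 for B cells, -0.05 for erythroid cells and -0.10 for mast cells. This test took out the mean over the lists, so it argues only against an equal rise of all 10. A lower share of tumour cells with unequal gains of the other cells stays open. The title style alone is argued against by the mean of the 4 scores with labels exchanged within styles, which stayed higher (exact permutation p = 0.000541; 0.42 with p = 0.190 among the hyphen-titled arrays, where 21 splits exist, and 0.75 with p = 0.00253 among the others). It also stays open that the treatment may have changed the number of these cells in the tumour, or the RNA that they or the tumour cells hold. This was found and tested on the same tumours and is a hypothesis.

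Skeletal muscle genes were higher in responders as a list (adjusted p = 0.422 with an estimated correlation), and muscle tissue in some of the tumour pieces may account for it. The 20 muscle genes, 0 of them on another list, went up and down together within the groups (mean correlation 0.617, above each of 100 random lists, highest 0.085). Genes of other lists did so too, with estimated correlations of 0.654 for adipocyte, 0.528 for matrix and 0.478 for hypoxia genes. Some lists did not, such as milk protein genes at 0.0082. Of the muscle genes, Acta1 and Ckm stood below the reference RNA in responders, at -1.998 and -3.16 as group means, and above the non-responders by 1.30 and 1.08. The group mean of Myh4, given above with its wide spread, stood above the reference in responders and below it in non-responders. Neither the correlation nor values below or above the reference can tell muscle tissue from another shared cause, so muscle tissue stays open. A difference carried by 1 responder alone is argued against, since the score differed by 0.99, 0.80 and 1.67 without responders 1, 2 and 3 (highest exact permutation p 0.0364), but 2 responders carried it (scores 1.42 and 1.79), while responder 3 (0.07) lay among the non-responders. The title style stays open: within the hyphen-titled arrays, with only 2 non-responders, the score differed by 0.58 (exact permutation p = 0.5 over 10 splits), and the list median of 1.01 with the style as a block takes the style to act alike in each group, although hyphen-titled arrays differed from the others by -0.75 in untreated tumours and 0.74 in non-responders. An effect of the response itself was not tested apart from these and stays open.

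Genes lower in treated tumours spanned more of the genome (median 31522 bases, 268 genes) than genes higher in them (13301 bases, 409 genes) or the others (19008.5 bases). The permutation p of lower against higher genes was 1.000e-05, the smallest the permutations can give. These permutations exchanged labels between genes and took the genes as independent, so this p does not measure the spread between tumours. Without the members of the fixed lists the medians were 32936 bases (259 genes) and 13888 bases (377 genes), with a permutation p over genes of 1.000e-05, likewise the smallest. Few of the called genes were members, so only the listed genes themselves are argued against as the source. Immune and matrix genes outside the lists were not tested and stay open. A trend of the values with span on each array is argued against as the whole cause of the calls: with it removed 618 genes passed in place of 677, 520 of them shared, 282 higher and 336 lower. The removal moved log2 differences by a median of 0.050 and at most 0.245, beside a median size of 0.78 among the genes that passed. A smooth trend this small could hardly have ended most calls, so the count adds little to these sizes. After that removal the medians were 21508.5 and 15461.5 bases, but removing the trend narrows this gap partly by construction, and the slopes of treated and untreated tumours differed with an exact permutation p of 0.0627, so such a trend may account for part of the gap. RNA quality is not analysed here and stays open, as does an effect of the treatment.

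Compared with other splits of the same tumours, chance was excluded for the genes that passed in treated tumours (678, highest other 2) and in non-responders against untreated tumours (283, highest other 1), each with 1 of 100 splits as large, the real one. Excluding chance does not tell the treatment from cohort, age or time of harvest, which were not taken into account. For responders against untreated tumours 3 of 100 splits gave as many as the 14 genes (highest other 44). Of the 100 splits, 1, the real one, gave as many as the 2995 genes at an unadjusted p under 0.05 in limma (highest other 2825). The limit set before the data were examined was fewer than 5 of 100 splits, and these shares fall under it. None of the shares was adjusted for the number of counts compared. Since other splits reached 14 genes, chance is not called excluded for that count. These splits ignored the title style, with which all responders go: 1 gene passed with the style as a block, 0 within the hyphen-titled arrays (limma, 1707 at an unadjusted p under 0.05), and 3 without any one of 8 single arrays. What lies behind the split with 44 genes beside the real 14 was not tested. For responders against non-responders the real count in limma was 0, which all 100 splits reach whatever the groups (highest other 27), but 17 of 100 also gave as many as the 1174 genes at an unadjusted p under 0.05 (highest other 1976), so chance was not excluded. For 3 against 2 weeks the count in limma was likewise 0 (all 100 splits, highest other 5), and 47 of 100 gave as many as the 830 genes at an unadjusted p under 0.05 (highest other 2377), so chance was not excluded. Chance was not excluded for the number of lists that passed: 12 in treated tumours (17 of 100 splits, highest other 17), 4 in responders (81 of 100, highest other 15) and 5 after 3 weeks (81 of 100, highest other 16).

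Among untreated tumours, replicate 4 stood apart for Arg1 (gap over range 0.609; -4.27, next -2.03), Eomes (0.665; 2.41, next 0.84), Krt17 (0.746; -1.02, next 0.72) and Irf9 (0.634; 0.37, next 1.59). It did so for the p53 score (0.573; -0.66, next -0.31) and the EMT score (0.577; -1.31, next -0.56) as well. Untreated replicate 7 stood apart for Egr2 (0.608; 2.30, next 3.83), Vldlr (0.583; -1.10, next 0.13), Ei24 (0.585; 0.05, next -0.44), Plin4 (0.685; -0.45, next -4.06) and Cidec (0.832; -0.09, next -4.88). Untreated replicate 1 stood apart for Gucy2e (0.734; 1.82, next 0.27) and Lyrm7 (0.787; 0.36, next -0.09), and untreated 3 for Col12a1 (0.762; -2.43, next -0.19) and the luminal score (0.667; 0.53, next 0.07). Untreated 5 did for Pnma2 (0.590; -0.36, next -1.27), untreated 6 for Eda2r (0.578; -1.55, next -0.61) and untreated 2 for Dcxr (0.651; -2.68, next -1.15).

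Among non-responders, replicate 2 stood apart for Eno3 (0.496; -4.49, next -5.15), Actn3 (0.626; -2.83, next -3.96), Dnajb9 (0.600; -1.10, next -0.27) and the muscle score (0.610; 1.02, next 0.05). Non-responder 4 stood apart for Shisa2 (0.499; -3.45, next -2.12), Eomes (0.558; -1.92, next -0.48) and the neutrophil score (0.514; 1.60, next 0.53). Non-responder 6 did for Ifit3 (0.624; 0.64, next 1.13) and Mapre3 (0.697; 1.60, next 0.10), and non-responder 9 for Col12a1 (0.651; -3.60, next -0.996).

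Lists that differed between groups of treated tumours in camera at the preset correlation, but not with an estimated correlation (adjusted p of at least 0.16), in fry or by adjusted exact permutation (smallest 0.245 and 0.665), were, in responders against non-responders, mitosis (median -0.33), skeletal muscle (1.06), squamous (0.62) and protein folding genes (0.34). In 3 against 2 weeks they were p53 target (-0.27), macrophage (-0.21), fibroblast matrix (-0.50), adipocyte (0.84) and basal genes (-0.27). Outside the genes analysed, 30 of 10263 spots without a named gene passed between treated and untreated tumours, 8 higher and 22 lower (smallest adjusted p 0.0120).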

How the results depend on the processing

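The settings with zeros kept as values, with the title style as a block or within a style, and without untreated replicates 2 and 4 were chosen after the data were seen, and the others before. No paired analysis was possible because the replicate numbers were given in accession order and mark no shared animal or batch. A random effect of the mouse was not run, since only 1 mouse gave 2 tumours. Signal over background is not analysed here, so the number of arrays sets the precision. Where a count below rests on fewer tumours or spots, the setting itself changed the power of the test, but some of these counts rose. The cause of a change in count was not tested in any setting.

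For treated against untreated tumours (678 genes), the count was 1313 with only spots measured on every array, 3 with 2-week and 0 with 3-week treated tumours (limma, 2906 at an unadjusted p under 0.05). It was 42 without untreated 2 and 4 (40 shared), 2 within the hyphen-titled arrays (0 shared) and 262 within the others (158 shared). It ran from 212 to 1183 when 1 array was left out, and from 497 to 969 in the other 11 settings. Of 3055 values of 85 named genes, 2492 kept their side of the threshold, 487 lost it, 70 gained it, 6 moved and 0 turned. The 12 lists became 0 with an estimated correlation, 13 on ranks (T and NK cells added) and 10 to 14 without 1 array. Of 810 list values 743 kept their side, 26 lost it, 18 gained it, 21 moved and 2 turned: outside the hyphen-titled arrays the muscle median was -0.16 and the squamous median -0.0095.

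For responders against non-responders, the 4 lists became 0 with an estimated correlation and in fry, 8 without the mouse that gave 2 tumours, 8 within the hyphen-titled arrays and 4 to 9 without 1 array. The 0 genes of limma (1174 at an unadjusted p under 0.05) became 1 without that mouse, 1 with 3-week tumours and 0 to 12 without 1 array. The adipocyte median turned to -0.64 within the hyphen-titled arrays (adjusted p = 0.031), 1 of 756 list values, of which 680 kept their side, 9 lost it, 18 gained it and 48 moved. Of 1085 gene values, 1073 kept theirs, 5 gained it and 7 moved.

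For 3 against 2 weeks, the 5 lists became 0 with an estimated correlation and in fry, 1 without that mouse, 8 with the title style as a block and 1 to 8 without 1 array. Of 567 list values 444 kept their side, 35 lost it, 21 gained it and 67 moved. The gene count was 0 in limma in every setting tried (830 at an unadjusted p under 0.05 as reported), and 845 of 845 values of named genes kept their side.

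For non-responders against untreated tumours (283 genes), the count was 694 with only spots measured on every array, 607 with array weights, 167 without that mouse, 0 within the hyphen-titled arrays (limma, 1325 at an unadjusted p under 0.05) and 33 to 607 without 1 array. For responders against untreated tumours (14 genes), it was 366 with only such spots, 25 with the most variable spot, 47 with a trend and a robust variance, 538 with array weights, 5 without that mouse, 39 with zeros kept, 1 with the title style as a block, 0 within the hyphen-titled arrays (limma, 1707 at an unadjusted p under 0.05) and 3 to 396 without 1 array.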

Other observations

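Tests in this part were all chosen after the data were seen: the genes that passed were first looked through by family, and the 3 lists were then made for families seen among them, such as cathepsins, centromere proteins and zinc finger proteins, so their direction is not independent evidence. Genes of lysosomal enzymes, which break down macromolecules in the lysosome, were higher in treated tumours, 38 of 42 measured members positive with a median of 0.43. In all 11 passed over all genes, each of them higher: Ctsd (1.19), Npc2 (1.17), Hexa (1.13), Aga (1.05), Gusb (1.01), Ctsz (1.00), Ctsf (0.97), Fuca1 (0.96), Ctsc (0.89), Grn (0.85) and Ctsa (0.83). Their score was 0.19 ± 0.17 (SD) in 12 treated and -0.33 ± 0.26 in 7 untreated tumours (exact permutation p = 5.954e-05, 0.00012 within title styles, and p = 0.0102 in camera with an estimated correlation). That treated tumours hold more RNA of lysosomal enzymes may be followed up in other tumours; macrophages are rich in lysosomes, and whether the RNA comes from them was not tested.

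Genes of kinetochore and centromere proteins, which attach chromosomes to the spindle, were lower in treated tumours, with 27 of 33 measured members negative and a median of -0.33. Of those that passed, 8 fell, Cenpk (-1.23), Nsl1 (-0.91), Sgo2a (-0.89), Cenpq (-0.88), Cenpi (-0.86), Spc24 (-0.78), Hjurp (-0.65) and Incenp (-0.64), and 1 rose, Cenpt (0.64). The exact permutation p of their score was 0.00583 (0.00667 within title styles), and camera gave p = 0.058 with an estimated correlation. The list held 0 genes of the fixed lists, so kinetochore genes of the mitosis list such as Cenpe, Cenpf and Ndc80 were left out. The mitosis list itself fell by a median of -0.12, with an exact permutation p of its score of 0.144. Genes of zinc finger proteins had a median of -0.11, with 193 of 318 negative and an exact permutation p of 0.0443 (0.0518 within title styles, and p = 0.0891 in camera with an estimated correlation). Of these, 7 fell: Zfp948 (-1.11), Zfp704 (-0.87), Zfp639 (-0.87), Zfp131 (-0.85), Zfp566 (-0.63), Zfp935 (-0.60) and Zfp955b (-0.58). The 3 exact p were not adjusted for the number of lists that looking through the genes amounts to, so each is a hypothesis.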
